A study of Mus musculus with 12 samples.

How the data were processed

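Gene expression was measured in left ventricle of C57Bl/6 mice in 4 groups of 3 samples: wild type (WT) and Y955C, each young and old. Total RNA was extracted, copied to double-stranded cDNA and labelled with Cy3, per the labels' protocols, and each sample was hybridised to 1 NimbleGen expression array designed on mouse build MM9. The deposited values are RMA intensities, per the submitters' processing notes, which name RMA without a version. RMA corrects for background, makes the intensity distributions of arrays alike and summarises the probes of a transcript to 1 value. The software, its background model and its settings are not given in the sources used here. Per the file headers, each file holds an intensity per transcript beside an error of the summary. The intensities are on a linear scale and were the same in the per-array tables and in the series' value table. The error column is another kind of value, deposited with its scale unstated, and was not used here.

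Each array carried 44170 transcripts, 44155 of them read by 3 probes, and 1 control entry that averages 5000 random-sequence probes. The control entry was left out of all tests and used only as a measure of background. Through the gene identifiers in the array annotation, 39057 transcripts were named from a RefSeq table of assembly GRCm38, used for names only, and 5113 kept the name in the file. Coordinates are those of the files, on MM9. No annotation of that build was used here, so exons and untranslated regions are not described. A gene with several transcripts was represented by the transcript of highest mean log2 intensity over all arrays, which left 24172 genes. For 10216 of these genes, more than 1 transcript was measured.

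The log2 intensities were fitted with limma 3.58.1 in R 4.3.3: 1 mean per group, all 12 arrays sharing 1 estimate of spread per gene (8 residual and 5.4 prior degrees of freedom), with an intensity trend in the empirical Bayes step. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. The 7 comparisons were Y955C against WT in young and in old tissue, old against young in each genotype, the difference between those age effects, and each main effect averaged over the other factor. Errors of log2 differences are standard errors (SE) of this fit. Levels are means ± SD of log2 intensity.

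For each comparison, 32 gene lists were tested with camera at a preset correlation of 0.01 between genes, then with an estimated correlation and with fry, which asks whether a list's genes move on balance one way. Adjusted p-values for lists are over the 32 lists. Member counts are given over all genes and adjusted over the list alone. An exact permutation test of the list means, two-sided, with labels exchanged within age or within genotype, was added after the data were seen; with 3 arrays against 3 its smallest p is 0.1, and for the averaged comparisons, over 400 relabellings, 0.005. A further list of transcripts encoded by mitochondrial DNA matched no measured symbol and was not analysed here. Another 5 lists were added after the data were seen, and are used in the closing part only.

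The groups, comparisons, test, gene lists and the rule for naming genes were fixed before the data were examined. The rule took, for each simple comparison, up to 8 largest rises and 8 largest falls among called genes with an ordinary symbol whose groups did not overlap, or, with too few calls, the 4 smallest p-values in each direction as values. It took for each list up to 4 called members of largest change or up to 2 members of smallest p, for the interaction and the averaged comparisons the genes of smallest p, and always Polg with a short set of cardiac, mitochondrial and DNA methylation genes. Gdf15 and a few other genes shown per array were chosen after their values were seen, as is said where they appear. Not every gene the rule takes is reported here.

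The fitting was tested on simulated data with the spread and intensities of these arrays. There were 3 simulated sets with 200 changed genes each, among 24172. They covered every comparison except the difference between the age effects, for which recovery was not simulated. In a separate simulation of camera, a list of 30 genes shifted by 1 log2 unit was called in 20 of 20 sets, and 2% of unshifted lists had an unadjusted p under 0.05. Genes varied independently in these sets, so they do not show how camera acts on lists whose genes vary together. Alternatives covered the choice of transcript, a filter on dim genes, other scalings (cyclic loess, quantile, median), the intensity trend, a robust fit, array weights (statmod 1.5.0), the replicate number as a block, the position on the slide, only the 6 arrays of a comparison, and leaving out each array. For lists, only the scalings, the filter on dim genes, leaving out arrays and the other list tests were run. No list was tested with another choice of transcript, array weights or slide position. Leaving out the pair of arrays that correlated least with the others was added after the data were seen. So were the list tests among only the genes above the median intensity, and the medians of 20 classes of genes of like intensity set beside the changes of lists. The number of arrays limits the precision of every value.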

Results

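The left ventricle, the main pumping chamber of the heart, was compared between WT mice and mice carrying Y955C, a mutant form of polymerase gamma, the enzyme that copies mitochondrial DNA. Both genotypes were sampled young and old. The labels give neither the ages nor the sex. The series asks what a faulty mitochondrial polymerase and ageing do in the heart. The 12 arrays, 3 per group, each gave intensities between 8.45 and 42354 for 44170 transcripts, with medians between 169 and 196. The labels do not say that the samples of a group came from separate animals. The p-values therefore measure only the spread between these samples, which may be technical. The Y-linked gene Eif2s3y lay between 12.26 and 13.32 log2 intensity on all 12 arrays, and Xist, the RNA that silences an X chromosome in females, between 4.60 and 7.83. Ddx3y, also Y-linked, read 4.18 on Y955C-Young 1 and 9.33 to 11.93 on the other 11 arrays.

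The arrays were of unequal quality. Over all transcripts, Y955C-Young 1 had a median correlation of 0.716 with the other arrays and WT-Young 2 one of 0.844, against 0.897 to 0.957 for the rest. The random control probes read 48.3 and 40.3 on those arrays and 20.2 to 29.1 on the rest. The share of transcripts above the random probes ran from 74.9% on Y955C-Young 1 to 94.4% on Y955C-Young 3. All arrays sat on 1 slide, with the young samples at positions 1 to 6 and the old samples at positions 7 to 12. Age and that part of the slide therefore cannot be told apart, while the genotypes were mixed within each part.

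**Figure D1:**
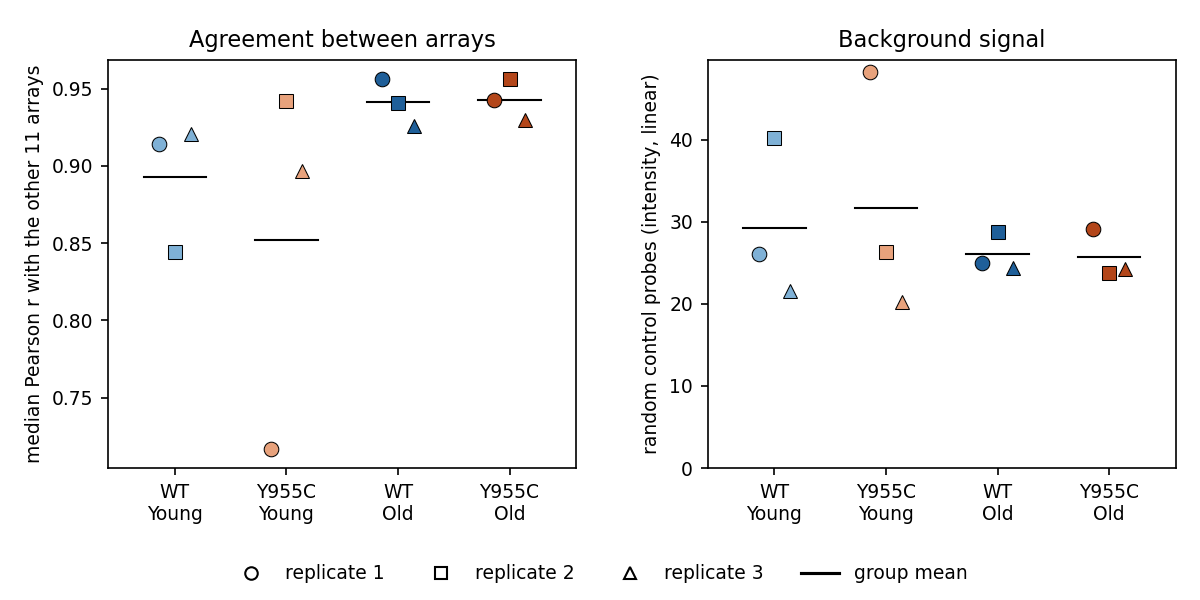
Left, the median Pearson correlation of each array with the other 11 arrays over all transcripts; right, the intensity (linear scale) of the random control probes. Symbols are replicates and lines are means of the 4 groups; Y955C-Young 1 lies apart in both plots, at 0.716 and 48.3.

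Polg, the mouse gene of the catalytic subunit of polymerase gamma, was read by 2 transcripts on chromosome 7. The brighter, at 86596472 to 86596914, lay at 13.39 ± 0.29 in young WT, 13.77 ± 0.43 in young Y955C, 13.12 ± 0.35 in old WT and 13.78 ± 0.53 in old Y955C (log2 intensity, mean ± SD, n = 3 each). The difference between genotypes was 0.37 ± 0.30 (SE) in young and 0.67 ± 0.30 in old tissue and passed the test in neither (limma, adjusted p = 1 in each). Whether these probes read the transcript of the mutant polymerase is not given in the sources used here, so Polg checks no label. Y955C-Young 3, at 13.34, and Y955C-Old 2, at 13.28, lay within the range of the WT arrays of their age, and the other 4 Y955C arrays lay above it. The dimmer transcript, at 86594267 to 86611073, ranged from 11.31 to 12.87 and did not order the arrays in that way.

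Old against young left ventricle, averaged over both genotypes, gave the most calls of the comparisons. A rise or fall with age below means a difference between old and young arrays, which also differ in slide position. Genes of mitochondrial fuel oxidation rose with age: of 31 measured genes of fatty acid oxidation, 23 rose and none fell (24 adjusted over the list alone), among them Acads, which opens the oxidation of short-chain fatty acids, by 2.02 ± 0.42 log2 units (SE), and Acot2, a mitochondrial thioesterase, by 1.93 ± 0.51. Of 21 genes of the TCA cycle and the pyruvate entry to it, 15 rose (16 adjusted over the list alone). These included Dlat, a subunit of pyruvate dehydrogenase, by 2.34 ± 0.36. The list also holds Mdh1, the cytosolic malate dehydrogenase, which rose by 1.32 ± 0.22. The mean change was 0.89 for the fatty acid list and 0.74 for the TCA list, against a median of -0.14 over all genes. Both lists passed with camera (adjusted p = 3.35e-11 and 4.01e-08), and for both the adjusted p = 0.385 with an estimated correlation.

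The direction of the age difference depended on how bright a gene was. The 12086 genes above the median intensity had a median age difference of 0.27, and the other 12086 one of -0.44. Intensities were also spread more widely on the old arrays: the interquartile range of log2 intensity over genes was 6.17 to 6.37 there and 5.14 to 6.13 on the young arrays. Genes as bright as the members of the fatty acid and TCA lists had median differences averaging 0.15 and 0.12, so 0.75 and 0.63 of the 2 means lay beyond what went with intensity. With only the genes above the median tested, a choice made after the data were seen, these lists passed camera with adjusted p = 2.64e-06 and 0.000124.

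Genes that build and maintain mitochondria showed the same direction. Of 78 proteins of the mitochondrial ribosome, 39 rose (49 adjusted over the list alone), with Mrps31 up by 2.87 ± 0.57 and Mrpl3 by 2.84 ± 0.46. Of 26 genes of mitochondrial DNA replication and maintenance, 11 rose and 1 fell, the same numbers adjusted over the list alone. Tfam, which packages mitochondrial DNA, rose by 1.47 ± 0.25, Opa1, which fuses inner membranes, by 1.80 ± 0.31, and Tefm, an elongation factor of mitochondrial transcription, by 2.40 ± 0.54. Ppargc1a, a coactivator of mitochondrial gene programmes, rose by 1.47 ± 0.26. Of 36 nuclear-encoded subunits of complex I, 10 rose (10 adjusted over the list alone), led by Ndufa9 (chromosome 6, 126771973 to 126799130), which went from 12.56 and 12.85 in young WT and Y955C to 14.41 and 14.26 in old. Of 41 subunits of complexes II to V, 11 rose (11 adjusted over the list alone), such as Uqcrc2 of complex III by 1.35 ± 0.18. The 4 lists passed with camera (adjusted p = 1.03e-12, 0.000144, 0.000149 and 5.62e-05 in that order). With an estimated correlation, none did (adjusted p = 0.385 for the ribosome and maintenance lists, adjusted p = 0.476 and 0.390 for the complexes). With only the genes above the median intensity tested, camera gave adjusted p = 2.64e-06, 0.0480, 0.0480 and 0.0364.

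Of 29 genes of oxidative stress defence, 12 rose and 1 fell (16 and 1 adjusted over the list alone), with the peroxiredoxin Prdx3, which removes peroxide in mitochondria, up by 3.05 ± 0.57 and the quinone reductase Nqo1 by 2.34 ± 0.38. Among 14 heat shock genes 5 rose (6 adjusted over the list alone), among them Hspb8 by 1.04 ± 0.25. Among 23 glycolysis genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), with Hk2, a hexokinase, up by 0.73 ± 0.21. Among 19 cell cycle genes 3 rose and 1 fell (3 and 0 adjusted over the list alone), with Ccna2, a cyclin, up by 1.97 ± 0.45. Camera gave adjusted p = 4.55e-05, 0.00979, 0.0241 and 0.0426 for the 4 lists, and adjusted p = 0.385, 0.385, 0.385 and 0.665 with an estimated correlation. With only the genes above the median intensity tested, oxidative stress defence kept its call (adjusted p = 0.0206). Heat shock, glycolysis and cell cycle genes lost theirs (adjusted p = 0.155, 0.330 and 0.648). The cell cycle list, with a mean of 0.61, lost its call without WT-Young 1 (0.58), WT-Young 3 (0.58), Y955C-Young 2 (0.63), Y955C-Young 3 (0.50), WT-Old 1 (0.46) or Y955C-Old 1 (0.40). The endothelial gene Vwf fell by 2.34 ± 0.38, though its list did not pass (adjusted p = 0.368). Nppb and Atp2a2, a stress hormone and the calcium pump of heart muscle, differed with age by 0.09 ± 0.12 and 0.14 ± 0.11 (adjusted p = 0.571 and 0.351), and the DNA methyltransferases Dnmt1 and Dnmt3a by -0.57 ± 0.26 and -0.03 ± 0.27 (adjusted p = 0.114 and 0.947). The list of cardiac stress and fetal genes had a mean of -0.34 (exact permutation, adjusted p = 0.168). Of its members, Nppa read 14.44 to 15.12 on the young and 12.98 to 14.57 on the old arrays. Myh7 read 13.49 to 14.36 and 12.60 to 14.12.

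**Figure D2:**
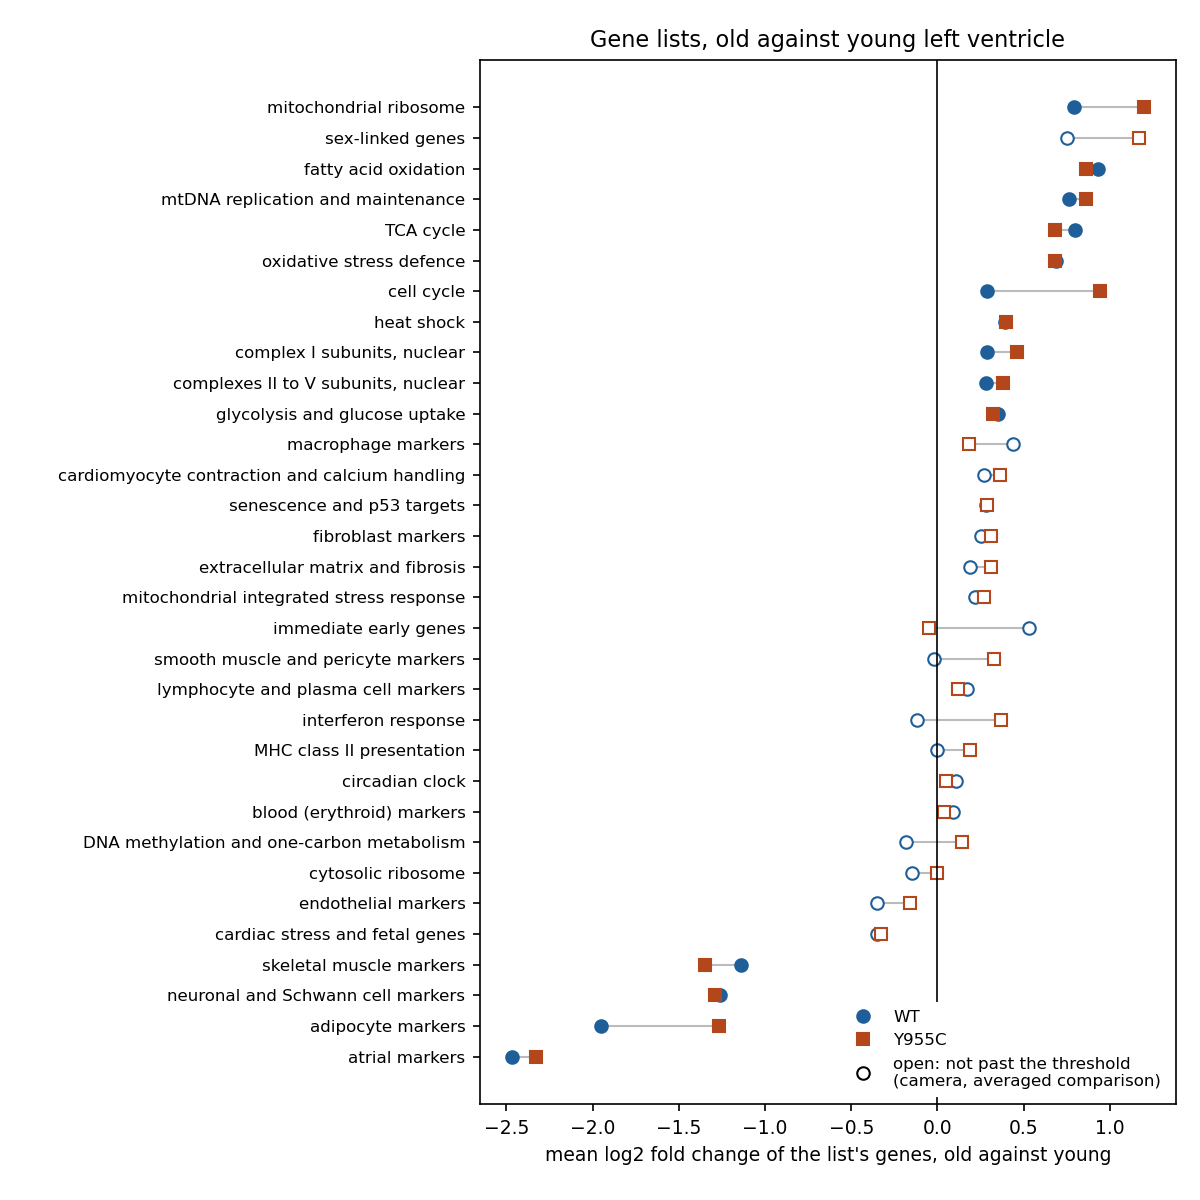
Mean log2 fold change, old against young, of the measured genes of each of 32 gene lists in WT (circles) and Y955C (squares); filled symbols are lists that passed camera at the preset correlation in the averaged comparison. Fatty acid oxidation lies at 0.93 in WT and 0.86 in Y955C.

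The smallest p-values of the averaged age comparison belonged to genes far apart in function. The ubiquitin-conjugating enzyme Ube2t rose by 4.02 ± 0.40 and Zfp367, a zinc finger gene, by 4.15 ± 0.43. The embryonic transcription factor Dux (chromosome 10, 57693398 to 57695423) and its relative Duxf3, which are multicopy genes whose probes may read several copies, fell by 5.04 ± 0.52 and 5.68 ± 0.57 (adjusted p = 0.000607 for all 4). In total, 6762 of 24172 genes passed, 3374 up and 3388 down, and 10210 had an unadjusted p under 0.05. Without WT-Old 3 the count was 4262, and without Y955C-Old 3 it was 4129. Of the genes named above as having risen or fallen with age, each kept its call whichever 1 array was left out. By camera 14 of 32 lists passed, by fry 13, by the exact permutation of list means 15, and with camera's estimated correlation 0. The permutation passed some lists that camera did not. These were contraction and calcium handling, with a mean change of 0.31, and sex-linked genes, fixed as a check on sex, with 0.96 (permutation, adjusted p = 0.0229 for both). The sex-linked mean was 0.75 in WT and 1.17 in Y955C.

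Markers of neighbouring tissues moved with age as well. Of 10 atrial markers, genes of the upper heart chambers, 5 fell and none rose (5 adjusted over the list alone): Myl7, the atrial light chain of myosin (chromosome 11, 5796643 to 5798781), by 5.80 ± 1.02, Sln, an inhibitor of the calcium pump, by 6.15 ± 1.21, and Mybphl, a myosin-binding protein, by 6.08 ± 1.17. Of 10 adipocyte markers 5 fell (5 adjusted over the list alone), such as Cidec, a lipid droplet protein, by 3.32 ± 0.75 and Ucp1, the uncoupling protein of brown fat, by 3.61 ± 0.79. Of 12 skeletal muscle markers 4 fell (6 adjusted over the list alone), and of 9 neuronal and Schwann cell markers 3 fell (3 adjusted over the list alone), with Th, the enzyme of noradrenaline synthesis, down by 2.18 ± 0.59. The mean changes were -2.40, -1.61, -1.24 and -1.28. Camera gave adjusted p = 0.0461, 0.0437, 0.0304 and 0.0437, and adjusted p = 0.665, 0.385, 0.385 and 0.385 with an estimated correlation. With only the genes above the median intensity tested, the atrial and skeletal muscle lists kept their calls (adjusted p = 0.0195 and 0.0480) and the adipocyte and neuronal lists lost theirs (adjusted p = 0.416 and 0.136). The atrial list lost its call without WT-Young 1 (-2.40), WT-Young 3 (-2.33), Y955C-Young 2 (-2.36), Y955C-Young 3 (-2.11), WT-Old 2 (-2.04), WT-Old 3 (-2.09) or Y955C-Old 1 (-2.43). The adipocyte list lost it without WT-Young 2 (-1.45), WT-Young 3 (-1.57), Y955C-Young 2 (-1.72), Y955C-Young 3 (-1.46), WT-Old 2 (-1.48) or Y955C-Old 1 (-1.71). The skeletal muscle list lost it without Y955C-Old 1 (-1.27), and the neuronal list without WT-Young 3 (-1.27), Y955C-Young 3 (-1.22), WT-Old 2 (-1.20), WT-Old 3 (-1.18) or Y955C-Old 1 (-1.32). The atrial genes were not low on every old array: Myl7 read 14.58 on WT-Old 1 and between 6.76 and 7.89 on the other 5, against 12.00 to 14.98 on the young arrays.

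Within WT the atrial mean was -2.47 (camera, adjusted p = 0.0305, with adjusted p = 0.613 with an estimated correlation). It was -3.82 without WT-Old 1, and the call was lost without WT-Young 3 (-2.32), Y955C-Young 2 (-2.47), WT-Old 2 (-1.74) or WT-Old 3 (-1.84). Within Y955C the mean was -2.33 and did not pass (adjusted p = 0.0844).

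**Figure D3:**
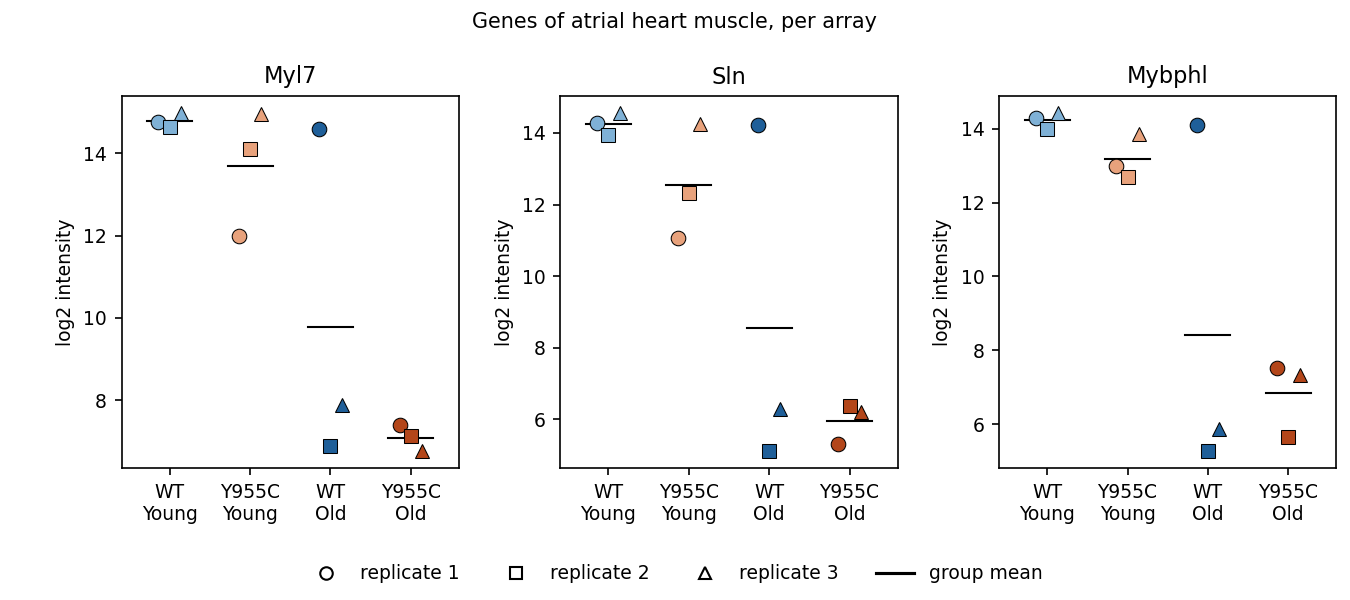
Log2 intensity of Myl7, Sln and Mybphl on each of the 12 arrays; symbols are replicates and lines are means of the 4 groups of 3. WT-Old 1, at 14.58 for Myl7, 14.23 for Sln and 14.10 for Mybphl, lies among the young arrays.

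Between old and young WT tissue, 2291 genes were called changed, 1221 up and 1070 down. The largest rises were in Cse1l, a nuclear export receptor, by 5.81 ± 0.88, Esrrg, an orphan nuclear receptor of oxidative metabolism, by 5.67 ± 1.11, and Fgf13, an intracellular fibroblast growth factor homologue, by 5.42 ± 0.77. The largest falls were in Duxf3 by 5.83 ± 0.81, in Flg, which encodes filaggrin of the skin, by 5.75 ± 0.89, and in the Prame-like gene Pramel36 by 5.44 ± 0.87. For Flg, 2 other transcripts were measured and lay on the other side of 0. Fatty acid oxidation genes rose in 13 of 31 cases (19 adjusted over the list alone), such as Cpt2, which passes fatty acids to the matrix, by 1.42 ± 0.32, and TCA genes in 6 of 21 (14 adjusted over the list alone). Of the mitochondrial ribosome 7 of 78 rose (7 adjusted over the list alone) and of mitochondrial DNA maintenance 4 of 26 (7 up and 1 down adjusted over the list alone), among them Tfam by 1.49 ± 0.35.

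These lists had mean changes of 0.93, 0.80, 0.79 and 0.76 in WT (camera, adjusted p = 3.65e-11, 5.00e-08, 5.00e-08 and 0.000489), and adjusted p = 0.555, 0.555, 0.593 and 0.555 with an estimated correlation. With only the genes above the median intensity tested, the maintenance list lost its call (adjusted p = 0.0548). In the WT comparison 6631 genes had an unadjusted p under 0.05, and in 44.5% of genes the 3 old and 3 young arrays did not overlap, where chance gives 10%. No gene passed without WT-Old 2 or without WT-Old 3 (limma, 0 each), and the count was 499 without WT-Young 1, 701 without WT-Young 2, 1123 without WT-Young 3 and 5692 without Y955C-Young 1. It was also 1425 without WT-Old 1.

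Between old and young Y955C tissue, 305 genes were called changed, 124 up and 181 down. Gal3st3, a sulfotransferase, rose by 4.70 ± 0.70, and Smco1, a membrane protein, by 4.86 ± 0.81. Alb, the serum albumin gene of liver (chromosome 5, 90889940 to 90905628), fell by 6.87 ± 0.89, from 11.41 ± 1.97 in young to 4.54 ± 0.23 in old Y955C, and Myl7 fell by 6.60 ± 1.45. On the 3 old Y955C arrays Alb, at 4.80, 4.35 and 4.46, lay below the random probes, at 4.86, 4.57 and 4.60, so the size of its fall depends on that floor. Of the mitochondrial ribosome 0 of 78 genes passed over all genes and 45 rose when adjusted over the list alone; of fatty acid oxidation 1 rose over all genes and 17 over the list alone. Mean changes were 1.20 and 0.86 (camera, adjusted p = 3.10e-16 and 8.09e-10), with adjusted p = 0.388 for both with an estimated correlation. Without Y955C-Young 1 the mitochondrial ribosome mean was 0.72.

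The Y955C age count moved with most arrays. At an unadjusted p under 0.05 there were 6209 genes, and 27.2% of genes had groups without overlap, where chance gives 10%. No gene passed (limma, 0 each) without WT-Young 1, WT-Young 3, WT-Old 3, Y955C-Old 1 or Y955C-Old 3, and 1 passed without Y955C-Young 3 or Y955C-Old 2. The count was 57 without WT-Old 2, 99 without WT-Old 1, 108 without Y955C-Young 1 and 4561 without Y955C-Young 2. The share of calls that were rises was 40.7%. Over the alternatives that keep all arrays it ran from 29.9% (quantile normalization) to 50.9% (array weights), and with more than 1 call left after leaving out an array, from 19.3% without WT-Old 2 to 56.5% without Y955C-Young 2. Only the 6 Y955C arrays fitted alone gave 0 genes.

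The age effects of the genotypes resembled each other. Of the genes called in each genotype, 119 rose in both and 159 fell in both, and none was called in opposite directions. Independent lists would share 6.3 and 8. The comparisons were not independent, since they share 1 estimate of spread per gene and the same parts of the slide. The excess over 6.3 and 8 therefore does not by itself show a shared effect of ageing. Across genes, which are not independent replicates, the log2 age differences correlated at r = 0.85, and 82.8% had the same sign. The difference between the age effects passed for no gene (limma, 0 of 24172; 122 at an unadjusted p under 0.05, and 1 gene with array weights). The smallest p was that of Alb, with an interaction of -7.89 ± 1.26 (adjusted p = 0.624) that rests on old Y955C readings below the random probes, followed by the fibrinogen gene Fgg at -2.39 ± 0.60 (adjusted p = 1). Without Y955C-Young 1, Alb passed at -6.77, and over 24 alternatives its adjusted p ran from 0.0103 to 1.

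In young tissue, no gene passed for Y955C against WT (limma, 0 of 24172), and 495 had an unadjusted p under 0.05, fewer than the 1209 that chance gives. The 4 genes of smallest p among those higher were Alb, Fga, Gc and Fgg, which encode plasma proteins made by liver. Alb differed by 6.18 ± 0.89 (adjusted p = 0.216), from 5.23 ± 0.54 in WT to 11.41 ± 1.97 in Y955C, Fga by 3.43 ± 0.75, Gc, a vitamin D carrier, by 2.65 ± 0.68 and Fgg by 2.09 ± 0.42 (adjusted p = 1 for these 3). Alb lay at 13.65, 10.61 and 9.97 on the Y955C arrays and at 4.61, 5.62 and 5.47 on the WT arrays. On WT-Young 1 Alb lay below the random probes, at 4.71, and on WT-Young 2 Fga, at 4.81, lay below theirs, at 5.33, so the size of these differences depends on that floor. With array weights limma called 1 gene, Alb. It was also the gene called without Y955C-Young 1, at 5.06 (adjusted p = 0.0443), in a range of 0.03 to 1 over 24 alternatives. In simulated data for this comparison, 6.97% of changes of 1 log2 unit and 59.1% of changes of 3 log2 units were recovered among 24172 genes, which is 14 and 117 genes over the 3 sets, beside 64 for changes of 2 log2 units. The same sets gave 52 false calls for this comparison and 35 for age in Y955C with the spread of each array as measured, and 2 and 3 with an equal spread.

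Several lists leaned one way in young Y955C tissue with no member past the test over all genes or adjusted over the list alone. Of 29 genes of the mitochondrial integrated stress response, which cells switch on when mitochondria fail, 21 were higher, with a mean difference of 0.71; Aldh18a1, an enzyme of proline synthesis, differed by 1.57 ± 0.67 and Phgdh, which opens serine synthesis, by 2.11 ± 1.08 (adjusted p = 1 for both). Camera gave adjusted p = 0.000401, with adjusted p = 0.846 with an estimated correlation. The exact permutation p was 0.4. The mean difference was 0.15 without Y955C-Young 2, where the call was lost, and 1.17 without Y955C-Young 3. Mean differences were -0.24 for complex I, -0.15 for complexes II to V, -0.43 for the mitochondrial ribosome, -0.14 for the cytosolic ribosome, -0.48 for interferon response genes, -0.39 for endothelial, -1.30 for atrial and -1.07 for adipocyte markers, and 0.53 for immediate early genes. These 10 lists passed camera at the preset correlation (largest adjusted p = 0.0131), and 0 passed with an estimated correlation (adjusted p = 0.846 for each) or by fry. Without Y955C-Young 1, the array of lowest quality, 1 list passed, that of the stress response.

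Single arrays changed the calls of these lists in young tissue. Without Y955C-Young 1 the means were -0.07 for complex I, -0.04 for complexes II to V, 0.05 for the mitochondrial and -0.07 for the cytosolic ribosome, 0.14 for interferon, -0.21 for endothelial, -0.63 for atrial and -0.96 for adipocyte genes and 0.01 for immediate early genes, with each of these calls lost. Without Y955C-Young 2 they were -0.43 for complex I, -0.28 for complexes II to V, -0.95 for the mitochondrial ribosome and -0.79 for interferon genes, and the calls of adipocyte (-0.86) and immediate early genes (0.55) were lost. The calls of adipocyte (-0.74) and immediate early genes (0.34) were also lost without WT-Young 2, and that of interferon genes without WT-Young 1 (-0.47) or WT-Young 3 (-0.27). Without Y955C-Young 3 the means were -0.79 for interferon and 1.03 for immediate early genes.

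In old tissue, no gene passed for Y955C against WT (limma, 0 of 24172, with 0 also under array weights), and 158 had an unadjusted p under 0.05, where chance gives 1209. The spread per gene was shared with the young arrays, including Y955C-Young 1, the array of lowest quality. The absence of calls therefore does not show that no gene differed. Genes of smallest p were Neat1, a long noncoding RNA of nuclear paraspeckles, at 0.89 ± 0.27, and Zbtb16, a zinc finger repressor, at -2.07 ± 0.52 (adjusted p = 1 for both); another transcript of Zbtb16 lay on the other side of 0. The uroplakin gene Upk3b, a mesothelial marker, lay at 9.49 in WT and 6.08 in Y955C, a difference of -3.40 ± 0.93. Of the 29 stress response genes 24 were higher, with a mean difference of 0.76 and, among members, Mthfd2, a mitochondrial enzyme of one-carbon metabolism, at 2.64 ± 1.06 and the pseudokinase Trib3 at 1.58 ± 0.64 (adjusted p = 1 for both). Camera gave adjusted p = 6.53e-09, with adjusted p = 0.471 with an estimated correlation, and the exact permutation p was 0.3. The mean difference was 0.45 without Y955C-Old 1 and 1.28 without Y955C-Old 2.

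The other lists that passed camera in old tissue had mean differences of -0.20 for fatty acid oxidation, -0.33 for macrophage, -0.20 for endothelial, -0.51 for skeletal muscle and -0.45 for erythroid markers, 0.46 for cell cycle genes and -1.16 for atrial markers. Of macrophage markers, Cd163, a scavenger receptor, lay -1.64 ± 0.53 apart (adjusted p = 1). Of the 32 lists 8 passed at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.417, for macrophage markers) or by fry. Calls were lost without WT-Old 1 for atrial (0.19), endothelial (-0.08) and skeletal muscle markers (-0.23), and without Y955C-Old 1 for cell cycle (0.04), fatty acid oxidation (-0.01) and erythroid genes (-0.32). They were lost without WT-Old 3 for fatty acid oxidation (-0.17), erythroid (-0.23) and cell cycle genes (0.30), without WT-Old 2 for cell cycle genes (0.30), and without Y955C-Old 3 for endothelial (-0.10) and skeletal muscle markers (-0.30). Values grew without WT-Old 2 or WT-Old 3 for atrial markers (-1.89 and -1.79), without WT-Old 3 for endothelial markers (-0.31), without Y955C-Old 3 for fatty acid oxidation (-0.31) and without WT-Old 1 or Y955C-Old 2 for cell cycle genes (0.77 and 0.73). The number of lists passed was 15 without Y955C-Old 2 and 13 without WT-Old 2. In simulated data for this comparison, 5.47% of changes of 1 log2 unit and 55.1% of changes of 3 log2 units were recovered.

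Averaged over both ages, Y955C against WT gave 0 genes (limma, also 0 under array weights), with 398 at an unadjusted p under 0.05. The stress response list had the smallest camera p of the 32 at the preset correlation: 27 of 29 genes were higher in Y955C, with a mean difference of 0.74 (camera, adjusted p = 1.17e-09), with adjusted p = 0.349 with an estimated correlation. Without Y955C-Young 2 its mean difference was 0.45. Its exact permutation p was 0.105; by that test erythroid (0.005, the smallest it can give), endothelial (0.025), adipocyte (0.075) and macrophage markers (0.085) had smaller p. A single list at 0.005 has adjusted p = 0.160 over 32 lists, so this test cannot pass a list alone, and it passed 0. For the stress response no member passed over all genes or adjusted over the list alone. Aldh18a1 differed by 1.33 ± 0.48 and Mthfd2 by 1.91 ± 0.75 (adjusted p = 1 for both). The arrays labelled Y955C were not alike: Mthfd2 lay at 13.73, 14.23 and 11.22 on the young Y955C arrays 1, 2 and 3 and at 14.02, 9.32 and 13.83 on the old ones, against 8.95 to 12.26 over the WT arrays. Gdf15, a stress hormone chosen here after its values were seen, lay at 12.70, 13.43 and 6.12, and at 13.72, 7.39 and 11.91, against 7.81 to 9.69 in WT.

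**Figure D4:**
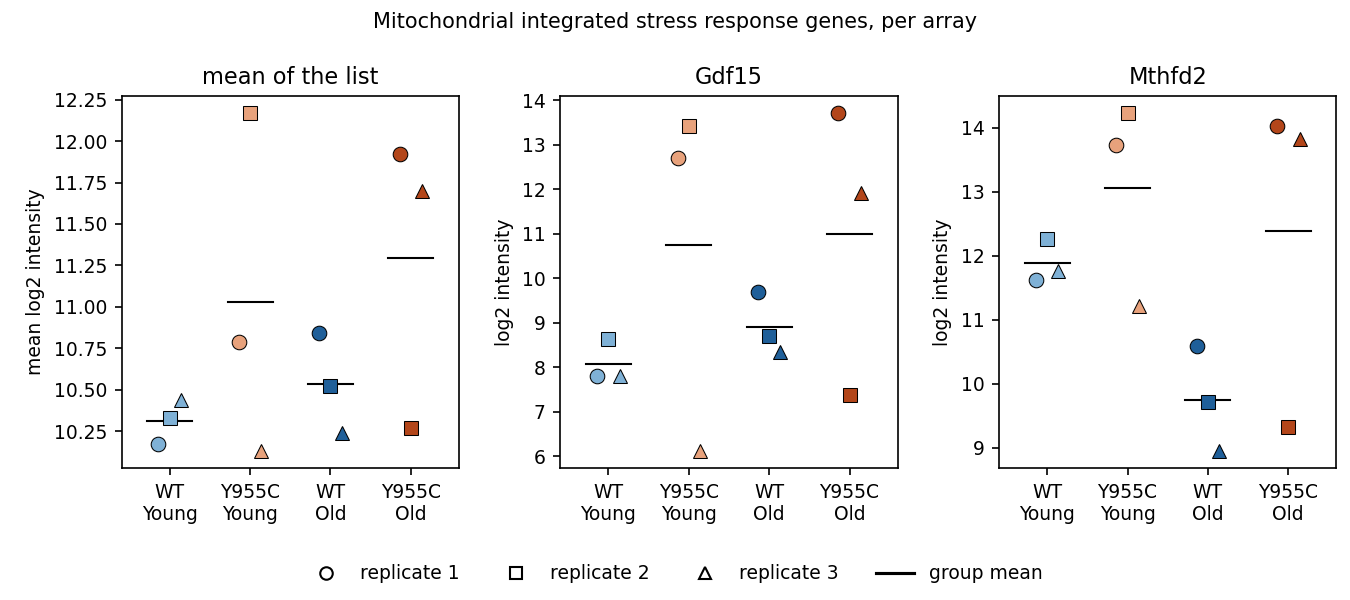
Mean log2 intensity of 29 genes of the mitochondrial integrated stress response, and log2 intensity of Gdf15 and Mthfd2, on each of the 12 arrays; symbols are replicates and lines are means of the 4 groups. Y955C-Young 3 and Y955C-Old 2, at 6.12 and 7.39 for Gdf15, lie at or below the WT arrays.

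Of the 32 lists, 12 passed camera for genotype averaged over both ages at the preset correlation, and 0 with an estimated correlation or by fry. Atrial markers had a mean of -1.23, complex I of -0.15, complexes II to V of -0.10, the mitochondrial ribosome of -0.22 and the cytosolic ribosome of -0.06 (largest adjusted p = 0.0208, and adjusted p = 0.834 with an estimated correlation for the cytosolic ribosome). Macrophage markers had a mean of -0.20, endothelial of -0.29, skeletal muscle of -0.41, adipocyte of -0.73 and erythroid of -0.42, and immediate early genes of 0.24. These passed camera with adjusted p = 0.0161, 0.000230, 0.0139, 0.00987, 0.0208 and 0.0399, and had adjusted p = 0.349, 0.349, 0.363, 0.349, 0.349 and 0.834 with an estimated correlation. Without Y955C-Young 1, 3 lists passed, and the means were -0.07 for complex I, -0.05 for complexes II to V, 0.02 for the mitochondrial and -0.03 for the cytosolic ribosome, with these calls lost. Without Y955C-Young 2 they were -0.25, -0.17 and -0.48 for the first 3. The mitochondrial ribosome also lost its call without Y955C-Young 3 (-0.20), and the cytosolic ribosome without WT-Young 1 (-0.05), WT-Young 3 (-0.07), WT-Old 3 (-0.05) or Y955C-Old 1 (-0.04). Without WT-Old 1 the atrial mean was -0.55. With only the genes above the median intensity tested, the macrophage, erythroid and cytosolic ribosome lists lost their calls (adjusted p = 0.0610, 0.231 and 0.102).

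Single arrays also changed the calls of the marker lists for genotype averaged over both ages. Endothelial markers lost theirs without Y955C-Young 1 (-0.20), skeletal muscle markers without Y955C-Young 2 (-0.24) or WT-Old 1 (-0.27), and adipocyte markers without WT-Young 2 (-0.56), Y955C-Young 1 (-0.67) or Y955C-Young 2 (-0.63). Macrophage markers lost it without WT-Young 3 (-0.17), Y955C-Young 1 (-0.14), Y955C-Young 3 (-0.19), WT-Old 1 (-0.16) or Y955C-Old 2 (-0.16). Erythroid markers lost it without WT-Young 3 (-0.39), Y955C-Young 1 (-0.39), Y955C-Young 2 (-0.40), WT-Old 3 (-0.31) or Y955C-Old 1 (-0.36). Immediate early genes lost it without WT-Young 2 (0.14), WT-Young 3 (0.25), Y955C-Young 1 (-0.02), Y955C-Young 2 (0.25), WT-Old 2 (0.15), WT-Old 3 (0.10), Y955C-Old 1 (0.11) or Y955C-Old 3 (0.18). Their mean was 0.49 without Y955C-Young 3, 0.45 without WT-Old 1 and 0.42 without Y955C-Old 2.

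The genotype differences at the 2 ages correlated at r = 0.09 across genes, with 51.3% of the same sign. Mybpc2 and Tnni2, genes of fast skeletal muscle fibres, differed by -0.71 ± 0.24 and -1.62 ± 0.51, and Tfam and Ppargc1a by -0.07 ± 0.25 and -0.19 ± 0.26 (adjusted p = 1 for all); the sign of Tfam flipped under cyclic loess.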

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

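The comparison of silent genes with genes as bright and the tests of array quality, label swaps, a single wrong label, atrial tissue and the array of lowest correlation alone were chosen only after the results were seen. Intervals in this part come from resampling genes with the arrays held fixed. They leave out the spread between arrays and treat the genes of a family as independent.

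The age effect differed between the genotypes by a test of the difference itself in 4 lists: mitochondrial ribosome by 0.41 log2 units (camera, adjusted p = 0.000976), cytosolic ribosome by 0.15 (adjusted p = 0.00152), complex I by 0.17 (adjusted p = 0.0266) and cell cycle genes by 0.65 (adjusted p = 0.0488). For each of these lists the adjusted p = 0.965 with an estimated correlation, and fry passed 0 lists. Genes as bright also differed in part. Their age differences averaged 0.1 in WT and 0.3 in Y955C for the mitochondrial ribosome, and 0.01 and 0.09 for the cytosolic ribosome. For complex I the interaction of genes as bright was 0.07, which leaves 0.11 beyond intensity. For cell cycle genes it was -0.04, which leaves 0.69. The mitochondrial ribosome value was -0.06 without Y955C-Young 1, 0.36 without Y955C-Young 3, both without a call, and 0.93 without Y955C-Young 2. Complex I lost its call without Y955C-Young 1 (0.01), Y955C-Young 3 (0.15), WT-Young 1 (0.15), WT-Young 3 (0.16), WT-Old 1 (0.16), WT-Old 2 (0.14), Y955C-Old 2 (0.13) or Y955C-Old 3 (0.16), and was 0.36 without Y955C-Young 2. Cell cycle genes lost it without Y955C-Old 1 (0.23), Y955C-Old 3 (0.79), Y955C-Young 2 (0.68), Y955C-Young 3 (0.42), WT-Young 2 (0.52), WT-Young 3 (0.71), WT-Old 2 (0.49) or WT-Old 3 (0.50), and the cytosolic ribosome without Y955C-Young 1 (0.08) or Y955C-Old 3 (0.12). The number of lists was 2 without WT-Young 3 and 7 without Y955C-Young 2. Of 100 splits of the arrays, 91 gave as many lists and the highest other gave 18, so chance is not excluded; for genes the real count was 0 (limma, 122 at an unadjusted p under 0.05), which all 100 splits match by construction, so it says nothing about chance; the highest other gave 1.

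The mean of the 29 stress response genes lay above every WT array of its age on 4 of the 6 arrays labelled Y955C. On Y955C-Young 1 it did so only at 10.79 against 10.44. Of the members shown per array, Trib3, at 12.40, and Fgf21, at 5.73, lay inside the young WT range there. Mthfd2, at 13.73, Aldh18a1, at 12.02, Asns, Phgdh, Psat1 and Gdf15 lay above it. The mean difference in young tissue was 0.15 without Y955C-Young 2. Poor array quality as the whole cause is argued against by 2 old Y955C arrays that correlate well with the others and whose list mean, 11.92 and 11.70, lies above every old WT array. Among the WT arrays, 0 had a mean of the 29 stress response genes above the Y955C mean of their age. That does not exclude a swap of labels between 2 samples. A mutant sample without the response, under a WT label, would not be seen. A single wrong label, or a sample without the mutant polymerase, stays open, because no value here decides it: 2 arrays, Y955C-Young 3 and Y955C-Old 2, lay in the WT range of their age for the brighter Polg transcript, but whether its probes read the mutant transcript is not known and the dimmer one did not single out the same arrays. A response to the mutant polymerase that differs between samples is the biological explanation the design names, and it was not tested.

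The age difference in both genotypes included falls of genes that heart is not known to express. Genomic DNA in the young samples may account for part. The 69 genes of multicopy silent families had a median of -1.43 (95% interval over genes, -1.84 to -1.07). Their difference from genes as bright was -0.83 (-1.24 to -0.63). Single-copy silent genes, at -0.61 (-0.89 to -0.31), lay less far above the multicopy families than the bound set beforehand, so genomic DNA stays open. RNA of germline tissue in the young samples is tested by the same -0.61, which lies between its bounds and leaves it open too; genes as bright had a median of -0.51, and the difference of -0.17 (-0.55 to 0.11) does not set the silent genes apart. Atrial tissue in the young samples stays open because the test rests on 1 array. WT-Old 1 had atrial markers 0.24 above the young WT mean. Over 305 genes it lay 0.849 of the way to the other old WT arrays (interval over genes, 0.826 to 0.871). Ageing itself, and the slide positions that go with age, cannot be told apart here.

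Alb, Fga and Fgg read higher on each young Y955C array than on any young WT array, though none passed the test, while Apoh and Apob, other plasma protein genes, overlapped between the groups. In this comparison 4.7% of all genes had groups without overlap, where chance gives 10%. The array of lowest correlation was not alone for Alb itself, which on Y955C-Young 2 and 3 lay at least 4.36 above the highest young WT array. Alb was picked as the gene of smallest p, so it does not decide this for liver genes as a set. Liver RNA in these samples stays open. The 22 other liver genes had a median difference of 0.47, under the bound of 0.5 set against it. Its interval over genes, 0.13 to 1, crosses the bound. The median difference was 1.57 on Y955C-Young 1 and -0.04 on each of the other 2 arrays. Y955C-Young 1 also had the highest random probe signal, 48.3, and the list was dim, with a mean log2 intensity of 6.92. The 1.57 was not set beside genes as bright on that array, so it does not by itself show liver RNA. A biological effect of genotype on these genes was not tested.

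Other splits of the arrays bear on the counts. For old against young averaged over genotypes, the real split gave 6762 genes and the highest other 3160, with 1 of 100 splits as large, the real one included. Of 200 possible splits 100 were run. Chance is therefore unlikely for this count if the samples are independent, which the labels do not say. For its 14 lists chance is not excluded, with 10 of 100 splits as large and a highest other of 16. For genotype averaged over ages chance is not excluded for the 12 lists, with 25 of 100 splits as large and a highest other of 18. Its 0 genes (limma, 398 at an unadjusted p under 0.05; highest other 0) are matched by 100 of 100 splits by construction, which says nothing about chance. With 3 arrays against 3, 10 splits are too few for a share under 0.05. The real and highest other gene counts, with the splits as large, were 0 and 17 (10 splits) for genotype in young, 0 and 0 (10) in old, 2291 and 0 (1) for age in WT and 305 and 2 (1) in Y955C. For lists they were 10 and 13 (2), 8 and 18 (7), 11 and 13 (5) and 11 and 14 (5) in that order. The other splits passed a median of 6, 11, 10 and 10 lists in the same order.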

How the results depend on the processing

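Leaving out the 2 arrays of lowest correlation, leaving out each array for the lists, testing lists among the genes above the median intensity only, and the exact permutation of list means were chosen only after the data were seen. Of 206 values of named genes that passed, 192 kept their call under cyclic loess, 190 under quantile normalization, 198 with median centring, 163 without the intensity trend, 205 with array weights, 206 with slide position as a covariate and 161 with the mean of a gene's transcripts. Position was centred within each age, so this covariate could not adjust for the part of the slide that goes with age. Leaving out each array kept 1755 of 2472. No called gene or list turned its sign under the 3 scalings (loess, quantile, median), while 128 gene values called in neither did so when an array was left out.

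Genes past the test, main count first. WT age, 2291: every transcript tested 4401, array weights 9150, slide position 3839, without the 2 arrays of lowest correlation 4483, only its 6 arrays 5448. Y955C age, 305: mean of transcripts 512, genes above the median 490, cyclic loess 803, no trend 481, array weights 3339, slide position 553, without the 2 arrays 615, only its 6 arrays 0. Age averaged, 6762: every transcript 11763, genes above the median 4446, array weights 10338. Genotype in young and the interaction, 0 each: array weights 1 each. Testing every transcript or only brighter genes changes the number tested; for the others the cause was not tested. With the replicate number as a block, counts were 2223 for WT age, 428 for Y955C age, 6916 for age averaged and 0 for the 4 others. The labels do not say that samples of the same number belong together. Deviations from the group means correlated at a median of 0.092 between same-numbered arrays of different groups, and of -0.0255 between differently numbered ones.

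Without 1 array the ranges were 0 to 1 for genotype in young (1 without Y955C-Young 1), 0 to 5692 for WT age, 0 to 4561 for Y955C age, 0 to 1 for the interaction (1 without Y955C-Young 1) and 4129 to 8805 for age averaged. Lists ranged from 1 (without Y955C-Young 1) to 10 for genotype in young, 6 to 15 in old, 2 to 7 for the interaction and 3 (without Y955C-Young 1) to 13 for genotype averaged.

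Of the lists, an estimated correlation left 0 in each of the 7 comparisons. Fry passed 0 for genotype in young, in old and averaged and for the interaction, 5 for WT age (4 of them also passed by camera) and 6 for Y955C age (5 of them). The exact permutation passed 0 for genotype in young and in old and for the 2 single-genotype age comparisons, where 3 arrays against 3 cannot pass. It also passed 0 for genotype averaged, where at least 4 lists would have to reach the smallest possible p of 0.005 together, so that 0 says nothing about any single list. Without the 2 arrays of lowest correlation there were 3 for genotype in young and 7 averaged; median centring gave 2 for the interaction. Among genes above the median intensity, WT age gave 6 lists, against 11, and Y955C age 7, against 11. The calls lost in WT were mitochondrial DNA maintenance (adjusted p = 0.0548), complex I (0.205), complexes II to V (0.109), glycolysis (0.205), adipocyte (0.407) and heat shock genes (0.139). In Y955C they were mitochondrial DNA maintenance (0.0760), skeletal muscle (0.0755), neuronal (0.164), cell cycle (0.490) and heat shock genes (0.263). For the interaction complex I (0.169) and cell cycle genes (0.528) were lost, for genotype in young interferon genes (0.0606) and in old cell cycle genes (0.358). The stress response list (0.71 in young, 0.76 in old, 0.74 averaged) did not pass with an estimated correlation, fry or the permutation, which test the same means.

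Mean log2 differences of lists over the fits without 1 array: in young, interferon -0.79 to 0.14, mitochondrial ribosome -0.95 to 0.05, stress response 0.15 to 1.17 and oxidative stress -0.30 to 0.20. In old, atrial -1.89 to 0.19, immediate early -0.32 to 0.38, contraction -0.10 to 0.07, TCA -0.19 to 0.07 and extracellular matrix -0.37 to 0.31. For the interaction, mitochondrial ribosome -0.06 to 0.93 and oxidative stress -0.18 to 0.31. For genotype averaged, immediate early -0.02 to 0.49, mitochondrial ribosome -0.48 to 0.02 and oxidative stress -0.14 to 0.11. Without the 2 arrays of lowest correlation, signs turned for immediate early genes in young (0.53 to -0.18) and averaged (0.24 to -0.12) and for the mitochondrial ribosome in young (-0.43 to 0.01) and the interaction (0.41 to -0.02). With the mean of all transcripts, signs turned for Hadh (1.60 to -0.22) and Pdk1 (3.94 to -0.77) with age in WT, and for Pdk1 (3.38 to -0.34) and Cd4 (1.55 to -0.17) with age averaged; transcripts of these genes differ, and the cause was not tested.

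Another background model was not run, since probe intensities before RMA were not used here. Signal over background limits dim genes: 74.9% to 94.4% of transcripts lay above the random probes, and the share was lowest on Y955C-Young 1.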

Other observations

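The lists of mesothelial and of silent genes and the comparison with genes as bright were chosen only after the data were seen.

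Mesothelial markers, genes of the layer that covers the heart, moved with the atrial markers. Of 11 measured markers 6 fell with age averaged over both genotypes and none rose, with a mean change of -1.98. Between genotypes averaged over both ages the mean difference was -1.45, and none passed over all genes. The list means were 10.79, 10.30 and 11.13 on the young WT arrays and 7.82, 9.95 and 10.56 on the young Y955C arrays. In old tissue they were 10.55, 8.03 and 8.14 in WT and 7.91, 6.83 and 7.17 in Y955C. Of 623 olfactory receptor genes, sensory receptors of the nose, 154 fell and 1 rose with age, with a median of -0.53. Genes as bright as these had a median of -0.29, a difference of -0.21 (95% interval over genes, -0.25 to -0.17).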
